A study of Homo sapiens with 4 samples.

How the data were processed

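Libraries were made from MTA1 immunoprecipitates (2 libraries) and input chromatin (2 libraries) of HCT116 cells and sequenced as paired ends, per the labels' protocols. Reads were trimmed with cutadapt and aligned with Bowtie2 to GRCh38, per the submitters' processing notes, which give no versions. The peak names in the deposited lists are of the form that MACS writes; its version, settings and any filters are not given in the sources used here. Each deposited list gives the position of every peak and, in column 5, a score that the authors' peak caller assigned to it. The lowest score was 50 in both lists, which would correspond to a p of 1e-05 if the score were 10 times the negative log10 of p; the scale is not stated in the sources used here, so scores were used to rank, describe and filter peaks within a list. Across lists, scores were correlated over shared regions, and 1 weighting of list 1 to the scores of list 2 assumed a common scale. Peaks were called per replicate, not on pooled libraries, and the control of each list was taken from the number that its ChIP and control names share. The control is called input in the labels, and a further word in the names of the lists is not explained there. No read counts or values per library were analysed here, so depth is unknown and the spread between libraries could not be estimated. Fragments of a given size range were selected and amplified by PCR before sequencing, per the labels' protocols, and the effect on peak calls was not measured.

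Genes were taken from a RefSeq table of GRCh38 with 1 row per gene, which gives the ends of each gene without strand, exons or sequence. On chromosomes 1 to 22, X and Y it held 20037 protein-coding genes and 59679 genes of every type. The planned distance to the 5′ end was therefore replaced by the distance to either annotated end, a change made after the table was seen, and all reference to gene ends means a midpoint within 1000 bp of either end of a protein-coding gene. Peaks on other sequences, 39 in list 1 and 140 in list 2, were left out of the comparisons and are described separately. Positions are 1-based.

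Lists were compared by overlaps of at least 1 bp. Overlapping peaks were merged, and a merged interval with at least 1 peak of each list was a shared region. The expected overlap came from 1000 random placements of list 2 within its chromosomes, or 100 for the alternative with an overlap of at least 50%, between the first and last peak of each chromosome because chromosome lengths and gaps were not used here, with a one-sided permutation p. Shares at gene ends and in gene bodies were tested against 1000 placements of the same regions, two-sided, with Benjamini-Hochberg adjustment over the 4 positions of gene bodies. Because the 4 shares sum to the whole, the positions away from gene ends were also tested as shares of the regions there, a choice made after the data were seen. Such p values describe regions in these lists, not biological replicates. Gene lists (16 lists, 442 entries, all found in the gene table) were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment at 0.05, and against 10000 random lists matched on the density of gene ends within 100 kb. Chromosome density used the span from the first to the last annotated gene, and its correlation with gene density used a permutation test. Intervals of shares are 95% Wilson intervals, intervals of odds ratios are 95% Woolf intervals, and both cover counting error only. Genes not in a list were named by a fixed rule. Shared regions were ranked by the sum of their best ranks in both lists, and the rule took the 20 protein-coding genes with the best-ranked region at an end, the 5 best-ranked regions, up to 4 members of each gene list with the best-ranked region, and every NuRD subunit. The lists and the rule were fixed before the data were examined. Members of gene lists with peaks in list 1 alone, and the symbol families and gene types of the closing part, were picked after their values were seen.

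Alternatives were the better-scoring 50% of each list, overlap of at least 50% of both peaks, each list alone, windows of 500 and 3000 bp, any overlap in place of the midpoint, placement within 1 Mb or 50 kb, placement outside the longest gene-free interval of each chromosome, and genes of every type. Analyses that need sequence, repeats, exons or transcripts were planned but not run, namely GC content, motifs, repeat filters, matching on GC content, exon overlap and transcript starts. A fit with the replicate number as a block was also not run. The overlap and gene list tests were tested on simulated data, in which 1000 planted peaks among 32003 and their genes were recovered at 100% each, and 5.5% of 200 random gene lists were called among 20037 genes. The planted peaks of both lists lay around the same points close to gene ends, so this recovery was nearly fixed in advance. It checks the code alone. The random lists were larger than the gene lists and were called without adjustment. Power and error of the reported tests were therefore not measured. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.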

Results

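MTA1, a subunit of the NuRD nucleosome remodelling and deacetylase complex, was immunoprecipitated from formaldehyde-fixed HCT116 cells, an epithelial line from a human colorectal carcinoma. The series held 4 libraries, 2 from MTA1 chromatin immunoprecipitation (ChIP) and 2 from input chromatin used as control. The authors' peak calls formed 2 lists, and each list set 1 ChIP library against the control with the same number. List 1 held 32042 peaks with a median width of 712 bp (interquartile range 519 to 983 bp), and list 2 held 31079 peaks with a median width of 447 bp (391 to 516 bp). Peaks covered 26.1 Mb in list 1 and 14.7 Mb in list 2. The median score, which is the authors' own value for each peak, was 64.1 in list 1 and 60.6 in list 2. The lists carry no read counts, so the depth of each library is unknown and no value per library was analysed here. The labels do not say whether the replicates came from separate cultures. On chromosomes 1 to 22, X and Y, 32003 peaks of list 1 and 30939 of list 2 entered the comparisons.

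The first comparison asked which MTA1 peaks were found in both replicates. The best-ranked region of both lists lay at KMT2A, which encodes a histone methyltransferase. It spanned positions 118435723 to 118436887 of chromosome 11 (GRCh38), scored 2348.07 in list 1 (rank 1) and 1544.41 in list 2 (rank 2, among peaks on chromosomes 1 to 22, X and Y), and had its midpoint 187 bp from the lower-coordinate end of the gene. The next 4 regions lay at the ends of TOR1AIP1, which encodes a protein of the inner nuclear membrane, of USP5, a deubiquitinase gene, of FBXL19, an F-box gene, and of ORMDL3, a regulator of sphingolipid synthesis. Such shared regions were the exception, since 1124 of 32003 list 1 peaks (3.51%, 95% Wilson interval 3.32 to 3.72%) overlapped a list 2 peak by at least 1 bp. In 1000 random placements of list 2 within its chromosomes, 1.53 ± 0.0706% of list 1 peaks (SD) were overlapped, with a highest value of 1.79%. The ratio of observed to placed overlap was 2.29 (one-sided permutation p = 0.001, the smallest possible with 1000 placements). Overlapping peaks merged into 1114 shared regions with a median width of 894 bp. When list 2 was placed within 1 Mb of its own positions, 602.6 overlapping peaks were obtained, and the ratio was 1.87 (permutation p = 0.001, one-sided).

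Overlap between the replicates was more frequent at gene ends, here the positions within 1000 bp of either annotated end of a protein-coding gene. Of the 4668 list 1 peaks there, 345 overlapped list 2 (7.39%, 6.67 to 8.18%), against 779 of the 27335 list 1 peaks elsewhere (2.85%, 2.66 to 3.05%), an odds ratio of 2.72 (2.39 to 3.10). Among the 100 best-scoring list 1 peaks, 44% overlapped list 2 and 74% lay at gene ends. Among the 100 best-scoring list 2 peaks, 13% overlapped list 1 and 9% lay at gene ends. Of those 100 list 2 peaks, 41 lay in the longest gene-free interval of a chromosome, against 0 of the 100 list 1 peaks. The list 1 share of overlapping peaks fell from 8.06% in the best score decile to 2.69% in the last, and the share at gene ends fell from 30.4% to 9.03%. In list 2, the corresponding shares were 6.66% and 3.10% for overlap, and 6.72% and 3.30% for gene ends. Over the 1114 shared regions the scores of both lists were weakly related (Spearman rho 0.15, Pearson r of log10 scores 0.33, permutation p = 1e-04, two-sided, the smallest possible). Regions are not independent replicates, so this p describes the regions alone. At gene ends rho was 0.23 over 350 regions (p = 1e-04), and at the 764 other shared regions it was 0.07 (p = 0.047).

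**Figure D1:**
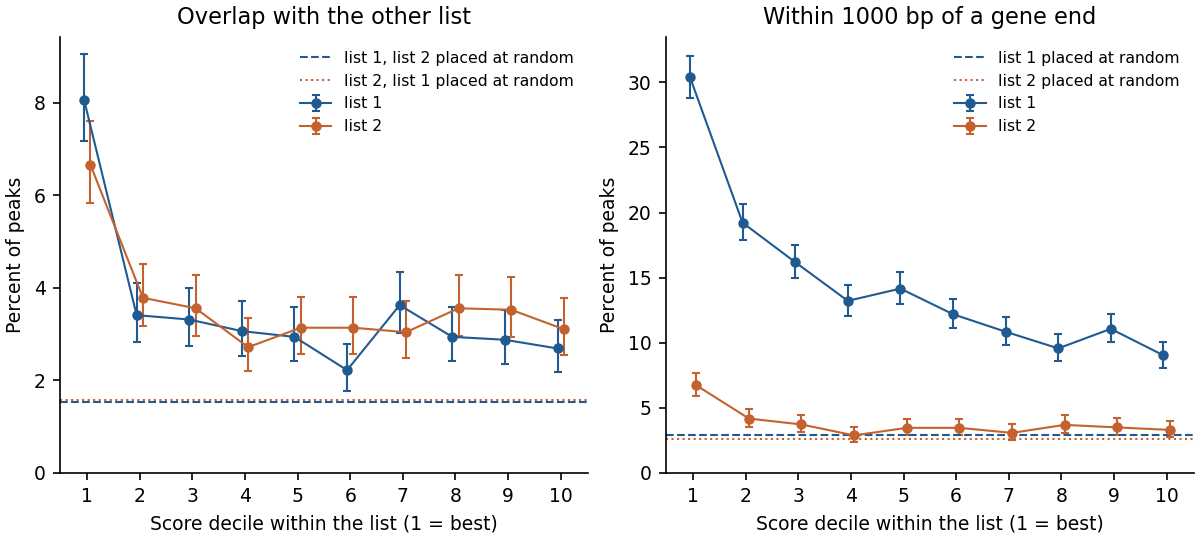
Percent of peaks overlapping the other list (left) and percent with the midpoint within 1000 bp of a protein-coding gene end (right), by score decile within each list, where decile 1 holds the best-scoring peaks. Points are shares with 95% Wilson intervals and horizontal lines are means over 1000 random placements; list 1 reached 30.4% at gene ends in its best decile, and list 2 reached 6.72%.

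The second comparison asked where MTA1 regions lay relative to genes. Shared regions gathered at the ends of protein-coding genes, where 350 of 1114 had their midpoint (31.4%, 28.8 to 34.2%), against 2.97 ± 0.515% (SD) in 1000 placements (ratio 10.6, two-sided permutation p = 0.002, the smallest possible). Each shared region holds a list 1 peak, and list 1 peaks were themselves frequent at gene ends (14.6%). Part of the ratio therefore carries over from list 1, and the placements do not allow for this. The replicates differed in their share at gene ends. In list 1, 4668 of 32003 peaks lay at gene ends (14.6%, 14.2 to 15.0%), which was 4.97 times the placed share (permutation p = 0.002, two-sided). In list 2, 1174 of 30939 did (3.79%, 3.59 to 4.01%), which was 1.45 times the placed share (permutation p = 0.002, two-sided). The odds ratio of list 1 over list 2 was 4.33 (95% interval 4.05 to 4.63). The median distance to the nearest gene end was 6.66 kb for shared regions, 15.1 kb for list 1 and 29.1 kb for list 2, against 50.3, 51.2 and 56.5 kb for their placements. When each midpoint was placed within 50 kb of its own position, the ratio was 4.88 for shared regions and 2.64 for list 1 (both permutation p = 0.002, two-sided), and list 2 no longer exceeded its placements (ratio 1.05, p = 0.0659, two-sided). List 2 peaks outside the shared regions had a share close to the placed one (2.78% against 2.61%, permutation p = 0.0619, two-sided). Taking out overlaps with list 1, whose peaks were frequent at gene ends, lowers this share by construction, so it adds no separate evidence.

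**Figure D2:**
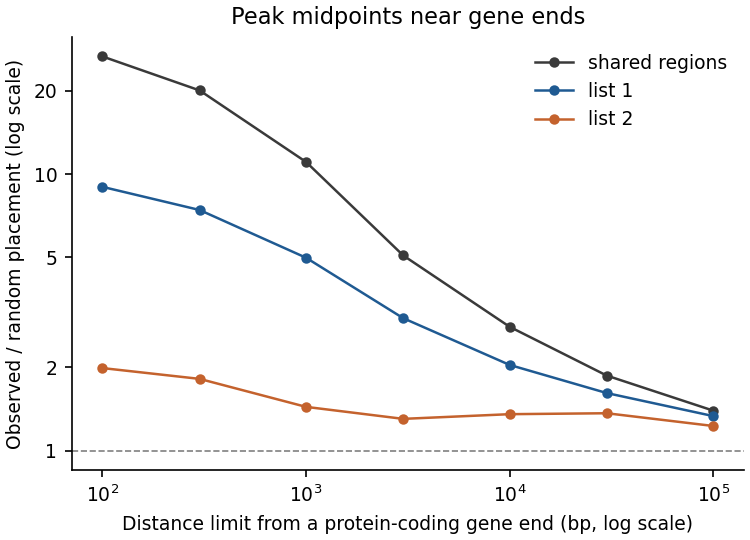
Ratio of the observed to the randomly placed share of midpoints (log scale) within 100 to 100000 bp of a protein-coding gene end (log scale), for shared regions, list 1 and list 2; the dashed line marks a ratio of 1. Within 100 bp the ratio was 26.7 for shared regions and 1.99 for list 2, with list 1 between them.

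Among the 764 shared regions away from gene ends, 455 lay inside a protein-coding gene (59.6%, 56.0 to 63.0%), against 44.1 ± 1.56% (SD) of placements away from gene ends (ratio 1.35). The space outside annotated genes held 237 of them (31.0%, 27.8 to 34.4%, ratio 0.736), and annotated genes that are not protein-coding held 72 (9.42%, 7.55 to 11.7%, ratio 0.687). Each had a Benjamini-Hochberg adjusted permutation p of 0.002 over 3 tests, two-sided, the smallest possible, and the 3 shares are complementary. The interior ratio on this base was 1.34 in list 1 and 1.18 in list 2 (adjusted permutation p = 0.002 each). As shares of all 1114 shared regions, the form planned at the outset, these positions held 40.8% (ratio 0.954, adjusted permutation p = 0.198), 21.3% (ratio 0.520) and 6.46% (ratio 0.485, both with an adjusted permutation p of 0.00266 over 4 tests), and the large share at gene ends lowers each of these ratios. Exons and introns were not told apart, because the gene table used here gives only the ends of each gene. Placements for all these shares ran over whole chromosomes, with gene-free intervals included, which lowers the placed share inside genes. No placement within 50 kb was made for them, so gene-rich neighbourhoods were not separated from a preference for gene interiors. Away from gene ends, 779 list 1 peaks overlapped list 2, against 493.6 when list 2 was placed within 1 Mb. Many of the 764 regions may therefore be chance overlaps.

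Of 20037 protein-coding genes, 4874 (24.3%) had a list 1 peak at an end, 1258 (6.28%) had a list 2 peak, and 522 had both, against 306.0 for independent lists (Fisher's exact test across genes, odds ratio 2.35, p = 1.2e-43, two-sided). A single peak can count for several genes, and closely spaced gene ends can raise the counts of both lists at the same genes. The exact test treats genes as independent, so its p value overstates the evidence. A shared region lay at an end of 400 genes (2.00%), against 36.2 ± 6.56 (SD) in placements with a highest value of 57. These placements do not allow for the frequency of list 1 peaks at gene ends. The 306.0 for independent lists does, but it is the counterpart of the 522 genes with a peak of each list. It is no baseline for the 400 genes, which need 1 merged region at an end. The 20 best-ranked of the 400 genes shared 15 regions, all at rank 151 or better in list 1 and rank 262 or better in list 2. Besides KMT2A, FBXL19, TOR1AIP1 with the neighbouring LOC139427322, USP5 with CDCA3, and ORMDL3 with LRRC3C, they were B4GALT7, ACSF3, GSPT1, AURKAIP1, RCAN1, JRK with PSCA, RTTN, KMT2B with ZBTB32, LETM1 and ZFR. KMT2B, a histone methyltransferase gene related to KMT2A, had its region at 35717147 to 35718507 of chromosome 19, with scores of 242.71 and 160.07. GSPT1, a translation termination factor gene, had scores of 446.49 in list 1 and 148.18 in list 2. RCAN1, a regulator of calcineurin, had 306.51 and 163.89, and B4GALT7, a galactosyltransferase gene, had 321.81 and 260.19. Among the 20 genes, the region midpoint nearest to a gene end was that of ACSF3, an acyl-CoA synthetase gene, at 4 bp. With an overlap of at least 50% of both peaks required, 13 of the 20 genes still held a shared region.

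None of the 15 NuRD subunit genes had a shared region or a list 1 peak at an end. CHD3, a remodelling ATPase of the complex, was the only one with a list 2 peak there, at 7884842 to 7885494 of chromosome 17, with a score of 52.47 and rank 26267. At MTA1 itself, 6 list 1 peaks and 1 list 2 peak lay within the gene, none of them at an end. Within MTA3 there were 3 list 1 and 12 list 2 peaks, within CHD5 8 and 1, within GATAD2A 7 and 0, within MBD3 3 and 0, and within CDK2AP1 1 and 0. HDAC1, GATAD2B and MBD2 each held 1 list 1 peak and 2 list 2 peaks, and RBBP4 held 1 and 3. MTA2, HDAC2, CHD4 and RBBP7 held no peak of either list. The absence of list 1 peaks at NuRD gene ends (0 of 15, upper interval bound 20.4%, against 24.3% of other genes) had an unadjusted p of 0.0299 and did not pass adjustment over 16 lists (Fisher's exact test, two-sided, adjusted p = 0.209).

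The third comparison asked which gene groups carried MTA1 regions at their ends, over 16 gene lists. Cytosolic ribosomal protein genes had the most shared regions, at 4 of 74 genes (5.41%, 2.12 to 13.1%, against 1.98% of other genes). These were RPS20 (scores 298.9 and 89.77), RPL6 (83.68 and 69.97), RPLP2 (474.07 and 59.26) and RPS7 (154.33 and 53.75). The RPL6 region lay nearer to an end of PTPN11 (7 bp against 119 bp). The RPLP2 region lay nearer to an end of PIDD1 (214 bp against 252 bp). The ribosomal list did not pass the test (Fisher's exact test, two-sided, p = 0.0606, adjusted p = 0.969). Splicing factors had 2 of 43, CELF1 (52.86 and 90.14) and SF3B2 (64.26 and 54.05). The CELF1 region lay nearer to an end of PTPMT1 (92 bp against 152 bp), and the SF3B2 region to one of PACS1 (302 bp against 662 bp). A single member had a shared region among mitosis genes (BIRC5, an inhibitor of apoptosis that acts at the spindle, 170.56 and 63.4, 1 of 26), DNA replication and repair genes (XRCC6, 52.8 and 64.07, with the region nearer to an end of DESI1, 1 of 30), epithelial-mesenchymal transition genes (MMP7, 66.05 and 72.92, 1 of 25), colon epithelium genes (CA2, 90.18 and 60.72, 1 of 25) and neuron and muscle genes (NEFH, 69.4 and 52.23, 1 of 25). No member did among 23 MTA1 targets from the literature, 26 p53 response genes, 20 Wnt targets, 22 AP-1 and immediate early genes, 22 hypoxia and glycolysis genes, or the blood (25), fibroblast and endothelial (20) and liver (21) markers. By Fisher's exact test, 0 of 16 lists passed for shared regions, with 0 at an unadjusted p under 0.05, and random lists matched on gene density also gave 0. With counts this small, differences of a few genes were not detectable.

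In list 1 alone, members with a peak at an end numbered 18 of 74 ribosomal protein genes, 10 of 43 splicing factors, 7 of 26 mitosis genes, 6 of 30 replication and repair genes, 4 of 25 colon epithelium genes and 4 of 26 p53 response genes. Wnt targets had 6 of 20, transition genes 7 of 25, AP-1 and immediate early genes 7 of 22, and MTA1 literature targets 5 of 23, which were SNAI1, BCAS3, GNAI2, WNT1 and TWIST1. None of these counts passed the test against 24.3% of all protein-coding genes. By Fisher's exact test, the lists lower at an unadjusted p under 0.05 were NuRD, hypoxia and glycolysis (1 of 22, EGLN3, p = 0.0255) and liver secreted proteins (1 of 21, APOC3, p = 0.0392), each with an adjusted p of 0.209. Blood markers had 5 of 25, fibroblast and endothelial markers 6 of 20, and neuron and muscle genes 9 of 25. The 4 lists of genes typical of other tissues together had 21 of 91 genes with a list 1 peak (23.1%, 15.6 to 32.7%), which did not differ detectably from other genes (24.3%, Fisher's exact test, two-sided, odds ratio 0.933, p = 0.903). In list 2, 0 of 16 lists passed, with 0 at an unadjusted p under 0.05.

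**Figure D3:**
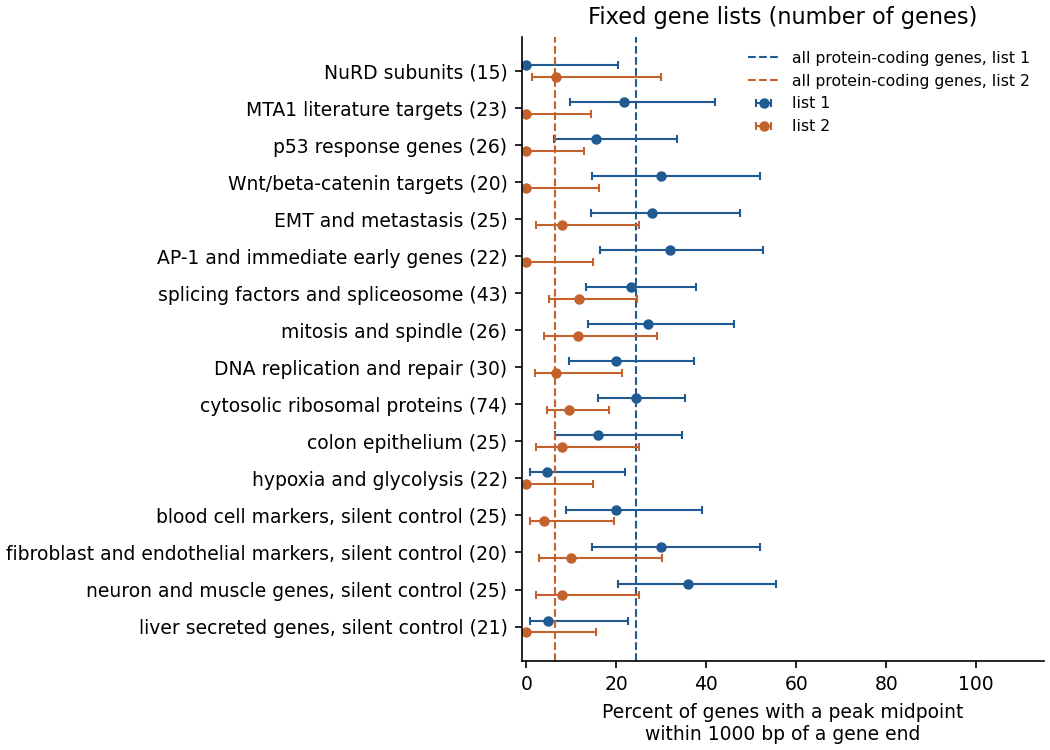
Percent of genes of each fixed list (number of genes in parentheses) with a peak midpoint within 1000 bp of a gene end, for list 1 and list 2, with 95% Wilson intervals. Dashed lines give all protein-coding genes, 24.3% in list 1 and 6.28% in list 2; no list passed the adjusted test.

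The last comparison concerned chromosomes. Chromosomes 19 and 17 had the highest density of shared regions, with 70 and 95 regions and 3.31 and 3.16 times the genome mean. Chromosome X had the lowest density apart from Y, which held no shared region. Only 2 shared regions, 172 list 1 peaks and 189 list 2 peaks lay on X, which were 0.0355, 0.106 and 0.121 times the genome mean. Density of shared regions differed between chromosomes (chi-square 414.8, p = 1.6e-73, across regions). Over the 22 autosomes, list 1 peaks per Mb followed protein-coding genes per Mb (Pearson r = 0.91, permutation p = 1e-05, two-sided, the smallest possible, adjusted p = 1.5e-05 over 3 relations, Spearman rho = 0.74, p = 0.00012). Without chromosomes 19 and 17, the farthest from the median, r was 0.74 (permutation p = 0.00012). For list 2, r was 0.75 (permutation p = 0.00085, rho = 0.49, p = 0.0229), but without chromosomes 19 and 17 it was 0.24 (p = 0.306), so that relation rests on those chromosomes. For shared regions, r was 0.89 (permutation p = 1e-05, rho = 0.70, p = 0.00039) and 0.70 without them (p = 0.00073). The copy number of chromosomes in these cells can shape peak calls. It was not analysed, and no density was corrected for it, that of X included.

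**Figure D4:**
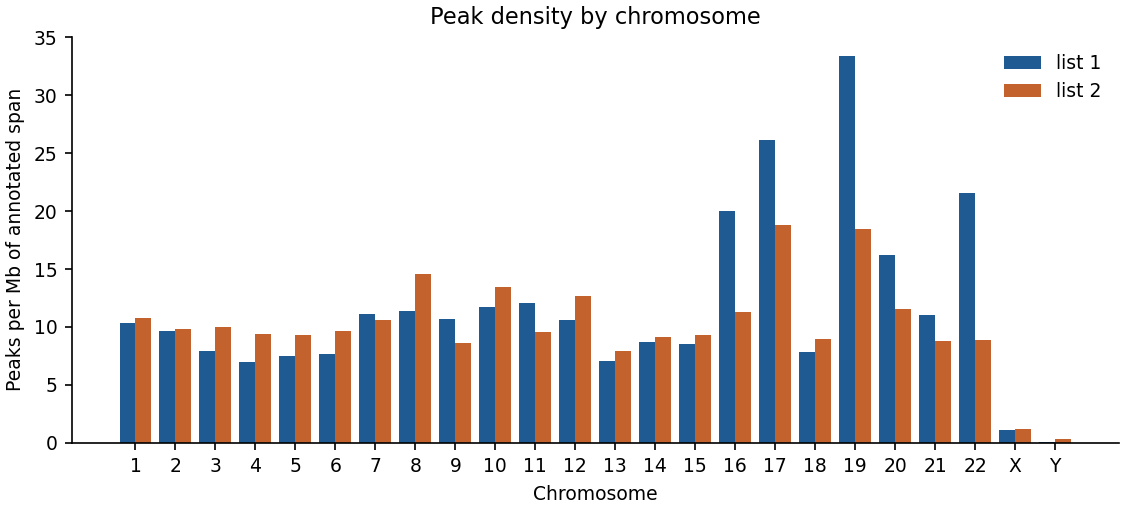
Peaks per Mb of annotated span on each chromosome for list 1 and list 2. Chromosome 19 reached 33.4 peaks per Mb in list 1 and 18.4 in list 2, and chromosome X had 1.10 and 1.21.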

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

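The tests of weak peaks, of gene-free intervals and unplaced sequences, of lower peak scores and of the lowest score decile, and the split of peaks by width, were chosen only after the results were seen. Peaks outside the assembled chromosomes were a signal in data that the comparisons did not use. List 1 had 39 such peaks on 21 sequences (0.122%), the best scoring 431.57 (rank 29) on the unplaced sequence KI270467.1. List 2 had 140 on 39 sequences (0.450%), and its best-scoring peak of all, 2350.28, lay on KI270438.1 from 103394 to 107421. These ranks count all sequences. Of the 100 best-scoring peaks over all sequences, 51 in list 2 and 2 in list 1 lay on such sequences or in the longest gene-free interval of a chromosome.

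Few peaks were shared by the replicates. Weak list 1 peaks near the score threshold are argued against only as the whole explanation, since 13.9% (11.9 to 16.2%) of the 1000 best-scoring list 1 peaks overlapped list 2. Overlap rose with score, to 44% of the 100 best and 60% of the 50 best, so weak peaks may be part of it. Strong list 1 peaks may also have been too weak to be called in list 2, which a ranking by list 1 score cannot show. Chance is argued against only as the whole of the overlap away from gene ends. The overlap there was 1.58 times that of placements within 1 Mb and above the highest of them. Placements gave 493.6 overlapping peaks against 779 observed, so chance could account for most of this overlap. A difference in depth or enrichment between the replicates may also contribute and stays open, because no read counts were analysed. No biological explanation was tested, as both lists come from the same group.

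Peaks of list 2 were rarely at gene ends. Peaks in gene-free intervals and on unplaced sequences were too few to account for this, at 250 of 31079 list 2 peaks (0.804%, 0.711 to 0.910%). For list 1 peaks picked by score rank alone, a likeness to list 2 peaks is argued against. In the lowest list 1 decile 9.03% (8.08 to 10.1%) lay at gene ends, against 3.79% of list 2. Width was not matched there. List 1 peaks no wider than the list 2 median (median score 57.4) had 4.23% at gene ends, and list 2 peaks of that width 2.29%. Whether list 2 peaks resemble list 1 peaks that are low in both width and score was not tested. Lower scores as such stay open: list 1 weighted to the score deciles of list 2 gave 13.0 ± 0.190% (SE), but this assumes that a score means the same in both lists, which no source states. A lower enrichment of the second immunoprecipitate might produce such a list and was not tested, and the same holds for differences in the control library.

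Peaks of list 1 gathered at gene ends. Gene-dense neighbourhoods are argued against as the whole cause, since the share was 2.64 times that of placements within 50 kb. Peak width alone is argued against by list 1 peaks no wider than the list 2 median, whose share of 4.23% was 1.39 times that of such placements (highest placement 3.76%). Wider peaks lay at gene ends more often in both lists, at 16.4% (15.9 to 16.8%) in list 1 and 5.30% (4.96 to 5.67%) in list 2, and among peaks no wider than that median list 1 (4.23%, 3.69 to 4.85%) also stood above list 2 (2.29%, 2.07 to 2.54%). Binding of MTA1 at gene ends and easier shearing or recovery of open or GC-rich chromatin could each give this pattern, and GC content was not analysed here.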

How the results depend on the processing

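The splits of the overlap and score correlation by gene ends, placement within 50 kb, placement outside gene-free intervals, genes of every type, shares among regions away from gene ends, matched random lists and the recount of the 20 best-ranked genes were chosen only after the data were seen. Over 12 results, 56 of 65 alternatives kept the direction and the side of the threshold, or a count within 1.5 times. The ratio of overlap to placements ranged from 1.58 (away from gene ends, placement within 1 Mb) to 6.25 (overlap of at least 50% of both peaks, 100 placements). The gene-end ratio ranged from 1.45 (all list 2 peaks) to 15.6 (shared regions, window of 500 bp). List 2 placed within 50 kb, which was not among the 65 alternatives, gave 1.05 and did not pass the threshold (permutation p = 0.0659, two-sided). The ratio for the interior of protein-coding genes, 0.954 and not past the threshold, turned to 1.17 and 1.18 with either list alone, and passed it at 0.754 in the better-scoring 50%. These changes follow the share at gene ends, since among regions away from gene ends the ratio was 1.35 in the main setting, 1.18 and 1.34 with list 2 or list 1 alone, and 1.34 in the better-scoring 50%. Genes with a shared region at an end, 400, became 1258 without replicate 1 and 4874 without replicate 2, which follows from no longer requiring both lists, and 198 in the better-scoring 50% and 239 with 50% overlap, which keep fewer regions. Of the 20 best-ranked genes, 13 remained with 50% overlap. No paired analysis was possible because each list already sets 1 ChIP library against its own control and no values per library were analysed. The repeat, transcript start, exon, GC and motif alternatives were not run. Depth is unknown, so its effect on which peaks were called was not measured.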

Other observations

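The tests by gene type, by symbol family and by paired ends were added once the files had been seen, and the pooled count of tissue marker lists was chosen after its lists had been counted. Genes that do not encode proteins also had peaks at their ends. In list 1, 1985 peaks lay within 1000 bp of an end of a long non-coding RNA gene (6.20%, 2.50 times the placed share), 169 at microRNA genes (ratio 3.61) and 24 at tRNA genes (ratio 2.79), each with an adjusted permutation p of 0.00233 over 7 gene types, two-sided. Shared regions were at long non-coding RNA genes in 94 cases (8.44%, ratio 3.35) and at microRNA genes in 16 (ratio 9.36), with an adjusted permutation p of 0.00466 each. List 2 had 747 peaks at long non-coding RNA genes (2.41%, ratio 1.00, adjusted permutation p = 1) and 54 at microRNA genes (ratio 1.34, adjusted p = 0.0979). Pseudogene ends held a small excess in list 2 (485 peaks, ratio 1.12, adjusted permutation p = 0.042) and in list 1 (554 peaks, ratio 1.19), and transcribed pseudogenes did in list 1 (112 peaks, ratio 1.87), both with an adjusted permutation p of 0.00233. Many of these genes overlap or adjoin protein-coding genes, and the shares were not separated from those. All ratios by gene type came from placements over whole chromosomes, and none was made within 50 kb. At protein-coding gene ends the list 2 ratio was 1.45 by whole-chromosome placement and 1.05 within 50 kb. The small pseudogene excesses may thus reflect gene-rich neighbourhoods.

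Gene families differed in how often they held a list 1 peak at an end. Among 98 families of at least 20 genes that share the letters of their symbol, 7 passed Fisher's exact test after adjustment. By that exact test, olfactory receptor genes (symbols starting with OR) had a peak at 10 of 392 genes (2.55%, adjusted p = 5.2e-32) and keratin-associated protein genes (KRTAP) at 2 of 94 (2.13%, adjusted p = 1.14e-07). Also lower by the exact test were beta-defensin genes (DEFB, 0 of 39, adjusted p = 0.000894), PRAMEF genes (0 of 23, adjusted p = 0.036), genes with CD symbols (9 of 91, adjusted p = 0.0159) and uncharacterised LOC genes (91 of 659, adjusted p = 7.82e-10). Mitochondrial ribosomal protein genes of the large subunit (MRPL) were the family that was higher, at 22 of 49 (44.9%, 31.9 to 58.7%, exact test, adjusted p = 0.0353). In list 2, where families were not tested, MRPL genes had 3 of 49 (6.12%) and DEFB genes 2 of 39 (5.13%), near the 6.28% of all protein-coding genes, while OR genes had 5 of 392 (1.28%) and KRTAP genes 0 of 94. The MRPL share in the list 2 counts was thus not raised, but the lists were not tested against each other. So few genes cannot exclude an excess in list 2. A shared region lay at an end of 2 of 49 MRPL genes, against 2.00% of all protein-coding genes. Whether members of a family are independent of each other was not tested.

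A hypothesis is that closely spaced gene ends hold list 1 peaks more often than single ends. Ends with another protein-coding gene's end within 1000 bp had a list 1 peak in 21.9% of 6684 cases (21.0 to 22.9%), against 11.4% of 33390 other ends (Fisher's exact test, two-sided, odds ratio 2.17, p = 2.6e-105). Each end of a pair was counted separately, so 1 peak can count at both. The exact tests here treat ends as independent, so their p values overstate the evidence. For shared regions the exact test gave an odds ratio of 1.80 (p = 8.5e-07), and for list 2 it gave 1.11 (p = 0.15). A peak drawn to the neighbouring end can fall in the same window, and a pair of ends that each attract peaks at the rate of single ends would give up to 21.6% in list 1, a value computed after the result was seen. For shared regions it would give up to 1.78%, against 1.60% observed, and for list 2 up to 6.21%, against 3.50%. The excesses at paired ends may therefore hold no more than this additive share. As a separate value, the pooled markers of other tissues, at 23.1% (15.6 to 32.7%), leave a moderate link between list 1 peaks and expression in colon cells neither shown nor excluded.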
